A study of Mus musculus with 8 samples.

How the data were processed

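White adipose tissue from the epididymal fat pad of C57BL/6J mice aged 16 weeks was measured by sequencing of polyadenylated RNA, with 4 samples labelled wild type (WT) and 4 labelled Mrp4 knockout. Per the labels' protocols, RNA was extracted with Trizol, mRNA was taken with poly-T beads, and paired reads of 100 bases were made on the BGISEQ-500 platform. Per the submitters' processing notes, the mouse genome build was mm9 and Bowtie2 was used; its version and the quantifier are not given in the sources used here. Per the file headers, the authors deposited an expected count, an FPKM value (fragments per kilobase of transcript, scaled to sequencing depth) and a transcript length for each gene of each sample, with NCBI Gene numbers. The expected counts deposited by the authors are estimates that need not be whole, and 92% to 92.6% of the genes listed in a sample had a whole number. A gene not listed in a sample's file was taken as 0. The deposited FPKM table of all samples held the FPKM values of the sample files, with a largest difference of 0. Each of the 18691 genes in the files had its own symbol.

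The expected counts were rounded to whole numbers and tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with the genotype as group, which left 14257 genes and removed 4434. Library sizes were scaled with TMM factors, and the groups were compared with the quasi-likelihood test (glmQLFit with robust=TRUE, glmQLFTest, two-sided) in a model with genotype alone. P-values were adjusted by the Benjamini-Hochberg method over these genes, with a threshold of 0.05. The standard error (SE) beside a log2 fold change is its size divided by the square root of the F statistic. FPKM values are given as mean ± SD over the 4 libraries of a group. Abcc4 was also compared by an exact two-sided permutation test on log2(FPKM + 1), for which 4 against 4 libraries allow no p below 0.0286. The total of expected counts was 14.1e6 to 14.7e6 per library. Reads carried no molecular identifiers. No use of strand is stated, so overlapping genes and antisense partners can share reads. Near-identical copies can share reads as well.

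Before the data were examined, 34 gene lists, the rule for named genes, the tests and the alternatives other than those called added were fixed. The lists were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, over the 33 lists with at least 5 tested genes, and again with an estimated correlation and with fry. The named genes are Abcc4; the 12 largest rises and 12 largest falls in log2 fold change among genes with an adjusted p under 0.05, a mean FPKM of at least 1 in the higher group and group ranges that do not overlap, passing over Gm, Rik and LOC symbols and pseudogenes; and in each list up to 4 members with the lowest p among those with a mean FPKM of at least 1 in either group. List members chosen this way that did not pass are counted, and of them only Upk1b is named. Not every gene that the rule names is reported. After the data were seen, 5 lists were added (liver, pancreas, kidney and intestine transcripts, and MHC class II genes). Only the liver and MHC class II lists had enough tested genes for camera, and their p-values were adjusted apart from the 33 lists. Also chosen after the data were seen were the 12 largest rises among genes with a mean of at least 5 FPKM in WT and of at least 10 FPKM over both groups, Dct, Tmem254c, Ide and its neighbours, Kdelc2 and the named MHC class II genes. Gene Ontology terms given in the files were tested with camera where they held 10 to 300 tested genes. The GRCm38.p6 annotation was used only for the order of genes, since its build is not mm9; 14228 tested genes were found in it by gene number.

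The scripts were tested on simulated data drawn for the tested genes from the means, library sizes and dispersions of these libraries, with 200 genes changed and 4 against 4 libraries. Over 14147 genes, edgeR recovered 81% of the changes of 1 and 90% of the changes of 2 on the log2 scale, where a changed gene lost to the filter counted as missed. Unchanged genes made up 8.06% of the edgeR calls, 7.69% of those of limma-voom and 19.1% of those of DESeq2, above the nominal share in each. With 1 list lowered by 0.5 on the log2 scale, camera called that list and 0 of the others. The simulated genes were drawn independently of each other, while the lists had a median estimated correlation of 0.19 in these libraries. The simulation thus does not show how often camera calls unchanged lists of correlated genes. Alternatives were the size factors of DESeq2 1.42.0, library size alone, upper quartile factors, 2 other filters, DESeq2 and limma-voom in place of edgeR, limma with trend on log2(FPKM + 1) and log2(FPKM + 0.1), the replicate number as a block, each library left out, and other thresholds. Added alternatives were a liver score as covariate, the liver transcripts left out, and removal of the trend with transcript length. Libraries of a group differed by more than counting noise, with a chi-square per degree of freedom of 12.7 to 60.9 over pairs, so none repeats another of its group. This does not tell separate mice from separate preparations of 1 mouse.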

Results

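The series compared white adipose tissue of WT mice with that of mice labelled as lacking Mrp4, an efflux transporter of the ABC family that exports cyclic AMP and prostaglandins and is encoded by Abcc4. Each group had 4 libraries, numbered 1, 2, 3 and 4 in WT and 1, 2, 4 and 5 in the group labelled Mrp4 knockout. The labels do not say that each library came from a separate mouse, so p-values measure only the spread between these libraries. Where a gene lost its call when some library was left out, the range of its log2 fold change without 1 library and the number of such cases are given in brackets, followed by the number of other scalings, filters, tools or units that ended the call, if any. Adjusted p-values are from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment unless another test is named.

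Abcc4 (gene 239273) was not lower in the libraries labelled Mrp4 knockout. Its level was 3.52 ± 0.232 FPKM in WT and 3.6 ± 0.244 FPKM in the libraries labelled Mrp4 knockout (SD, n = 4; exact permutation p = 0.571). Its expected counts ran from 271 to 316 in WT and from 262 to 320 in the other group. The log2 fold change was -0.05 ± 0.08 (SE), with a 95% interval of the fold from 0.843 to 1.11 (edgeR adjusted p = 0.692). The transcript level thus gave no support for the label, and every direction below rests on it. The counts are per gene and do not show which exons were read, and the structure of the altered allele is not given in the sources used here.

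**Figure D1:**
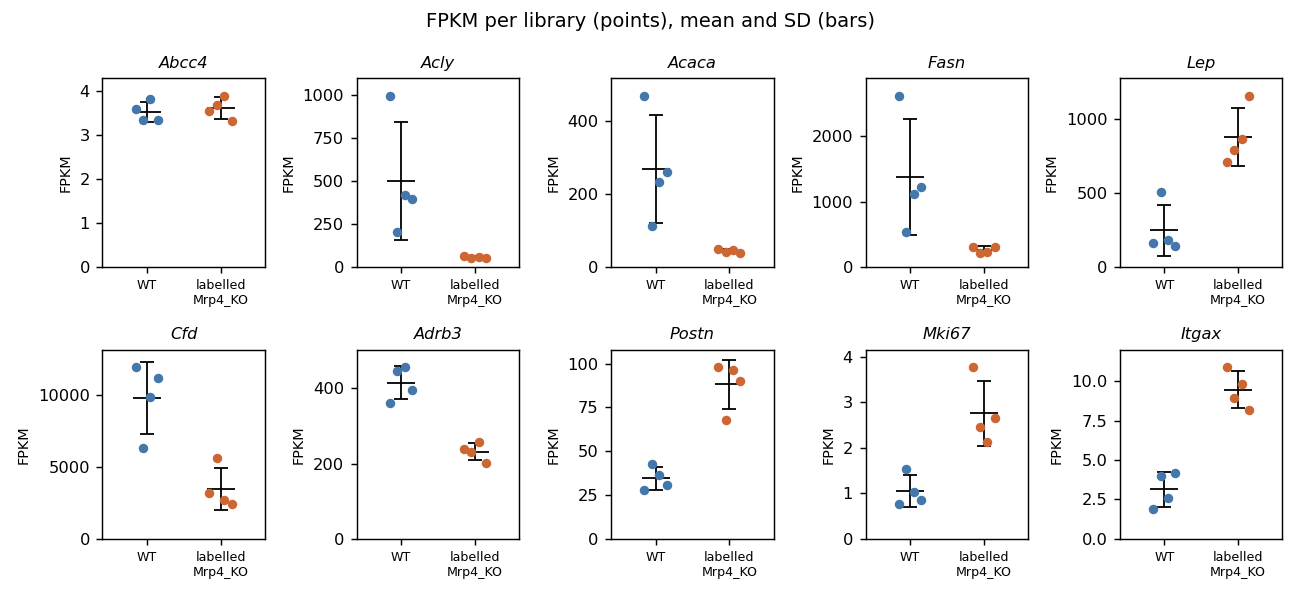
FPKM (vertical axes, linear from 0) of 10 genes in each library, with WT in blue and libraries labelled Mrp4 knockout in orange. Points are libraries and bars are the mean ± SD of 4. The groups overlap for Abcc4 and for no other gene shown.

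Most fatty acid synthesis genes were lower in the libraries labelled Mrp4 knockout. Over all, 2606 of 14257 tested genes differed (18.3%), 1458 higher and 1148 lower. The share higher was 55.9% and became 74.1% when libraries were scaled by size alone. The counts in each list below are to be read beside these shares. The number that differed was 1366, 3683, 1473 and 1172 without WT replicate 1, 2, 3 and 4, and 1474, 1654, 1380 and 1513 without replicate 1, 2, 4 and 5 labelled Mrp4 knockout. In the fatty acid synthesis list, of 18 genes 0 rose, 14 fell and 4 did not pass. 0 rose and 15 fell when adjusted over the list alone, with a median of -1.36 (camera adjusted p = 3.56e-09, adjusted p = 0.432 with an estimated correlation). Acly, which makes cytosolic acetyl-CoA from citrate, fell from 501 ± 343 to 56.6 ± 4.15 FPKM (-3.22 ± 0.43 on the log2 scale, adjusted p = 0.00211), Acaca, acetyl-CoA carboxylase, from 269.9 ± 149 to 43.8 ± 4.54 FPKM (-2.70 ± 0.37), and Fasn, fatty acid synthase, from 1369.9 ± 888 to 261 ± 53.5 FPKM (-2.46 ± 0.43). WT replicate 1 was highest for these genes, and without it the log2 fold changes were -2.64, -2.28 and -1.94. Acss2, Elovl6, Scd2 and Acacb also fell (-2.17, -2.14, -1.15 and -1.60), and without WT replicate 1 the values of Acss2 and Elovl6 were -1.73 and -1.60. In triglyceride synthesis, of 17 genes 0 rose, 7 fell and 10 did not pass. 0 rose and 8 fell when adjusted over the list alone, with a median of -0.40 (camera adjusted p = 0.00115, adjusted p = 0.432 with an estimated correlation). Mogat1 (-1.01) and Agpat3 (-0.36) fell, as did Agpat9 (-0.99, or -1.14 to -0.78 without 1 library, lost in 2) and Gpam (-0.60, or -0.75 to -0.53 without 1 library, lost in 3). In cholesterol synthesis, of 24 genes 1 rose, 8 fell and 15 did not pass. 1 rose and 10 fell when adjusted over the list alone, with a median of -0.32 or, without WT replicate 1, -0.15 (camera adjusted p = 0.00216, adjusted p = 0.612 with an estimated correlation). Pmvk, phosphomevalonate kinase, fell (-1.05), as did Nsdhl (-1.11, or -1.30 to -0.87 without 1 library, lost in 2) and Acat2 (-1.11, or -1.31 to -0.84 without 1 library, lost in 2). Of the 33 lists tested with camera, 11 passed, but 17 of the 35 splits of the libraries into 4 and 4 gave at least as many lists, and 0 passed with an estimated correlation. Without replicate 5 labelled Mrp4 knockout 17 lists passed.

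Genes of adipocyte identity, insulin response and respiration moved in part. In the adipocyte identity list, of 21 genes 1 rose, 5 fell and 15 did not pass. 1 rose and 5 fell when adjusted over the list alone (camera adjusted p = 0.144). Lep, which encodes leptin, rose from 247 ± 175 to 881 ± 197 FPKM (1.78 ± 0.40, adjusted p = 0.0191). WT replicate 2 lay above the other WT libraries for Lep; the log2 fold change was 2.38 without it, and did not pass without WT replicate 1, 3 or 4 or replicate 5 labelled Mrp4 knockout (1.62, 1.66, 1.59 and 1.61). Cfd, the protease adipsin, fell from 9813 ± 2510.0 to 3466 ± 1452 FPKM, Retn, which encodes resistin, from 2028 ± 329.6 to 1136 ± 196 FPKM, and the β3-adrenergic receptor gene Adrb3 from 415 ± 43.9 to 232 ± 23.9 FPKM (-0.90 ± 0.11, adjusted p = 0.000876). In adipokines, of 15 genes 2 rose, 5 fell and 8 did not pass. 4 rose and 5 fell when adjusted over the list alone (camera adjusted p = 0.845). Nrg4, a secreted neuregulin, fell from 41.9 ± 3.61 to 29.5 ± 1.52 FPKM. In adipogenesis regulators, of 23 genes 0 rose, 3 fell and 20 did not pass. 0 rose and 3 fell when adjusted over the list alone (camera adjusted p = 0.0703). The 3 were Srebf1 (-1.12), Stat5a (-0.49, or -0.59 to -0.38 without 1 library, lost in 5 and in 3 other settings) and Cebpa (-0.35, or -0.40 to -0.29 without 1 library, lost in 7 and in 5 other settings). In lipolysis, of 15 genes 0 rose, 5 fell and 10 did not pass. 0 rose and 5 fell when adjusted over the list alone (camera adjusted p = 0.0591); beside Adrb3 these were Plin1 (-0.35, or -0.37 to -0.32 without 1 library, lost in 4), Abhd5 (-0.58, or -0.71 to -0.52 without 1 library, lost in 5) and Ces1f (-0.58, or -0.69 to -0.49 without 1 library, lost in 6 and in 1 other setting) among the lowest p-values. In insulin and glucose handling, of 25 genes 2 rose, 8 fell and 15 did not pass. 2 rose and 15 fell when adjusted over the list alone, with a median of -0.32 (camera adjusted p = 0.000629, adjusted p = 0.432 with an estimated correlation). Tbc1d4, a regulator of glucose transporter movement, the insulin receptor gene Insr, the glycogen synthase gene Gys1 and the kinase gene Akt2 fell (-0.67, -0.41, -0.72 and -0.37). In oxidative phosphorylation, of 68 genes 0 rose, 35 fell and 33 did not pass. 0 rose and 49 fell when adjusted over the list alone, with a median of -0.36 (camera adjusted p = 8.74e-16, adjusted p = 0.502 with an estimated correlation). Ndufc2, Ndufs7 and Ndufb8 of complex I and Cox8a of complex IV fell (-0.42, -0.61, -0.39 and -0.45). In fatty acid oxidation, of 25 genes 1 rose, 4 fell and 20 did not pass. 1 rose and 4 fell when adjusted over the list alone (camera adjusted p = 0.0591). Members with the lowest p included Eci1 (-0.52), Hadh (-0.42), Echs1 (-0.55, or -0.65 to -0.47 without 1 library, lost in 2) and Acadvl (-0.50, or -0.60 to -0.41 without 1 library, lost in 5 and in 3 other settings).

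**Figure D2:**
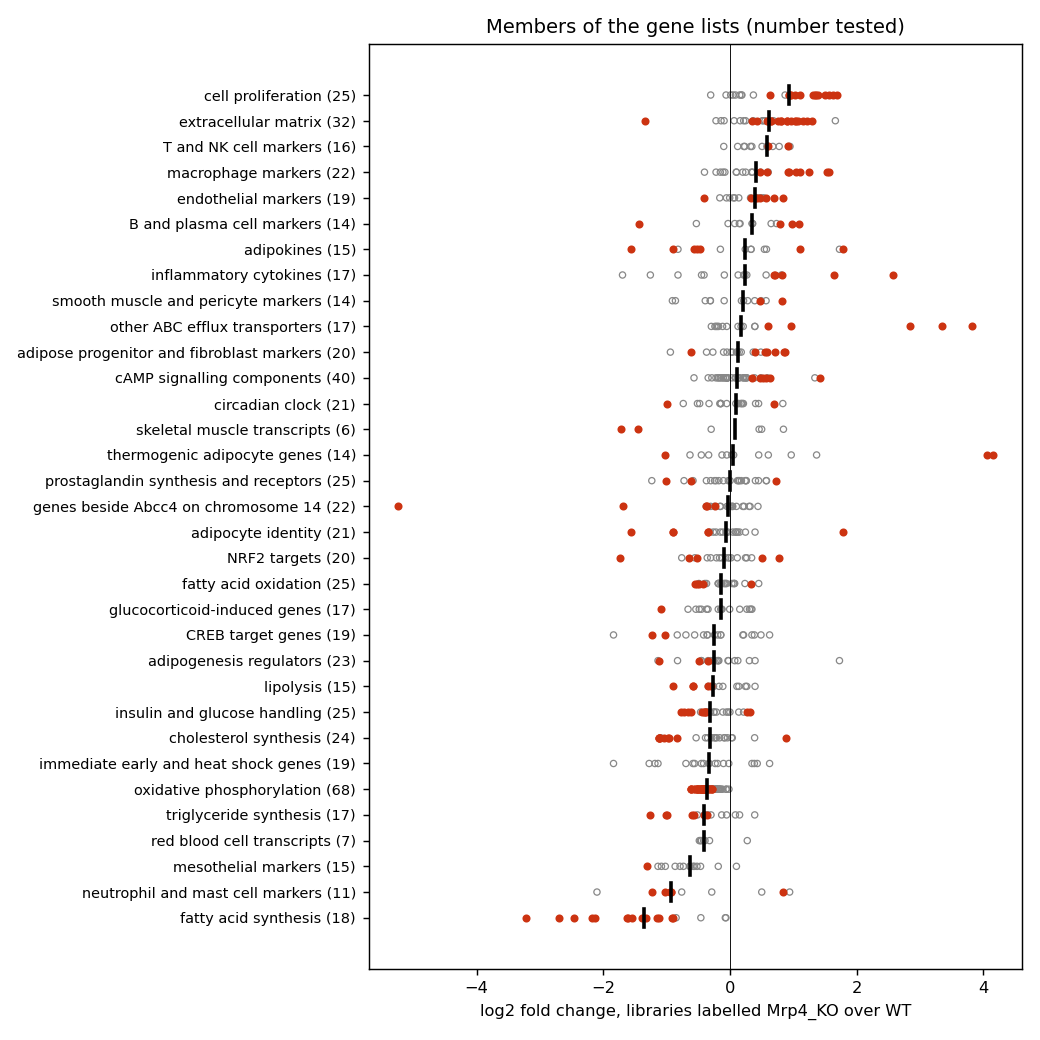
Log2 fold change (horizontal axis, libraries labelled Mrp4 knockout over WT) of each tested member of the 33 lists with at least 5 tested genes (number tested in brackets). Filled red points passed an adjusted p of 0.05, open points did not, and black bars are medians. Fatty acid synthesis has the lowest median, at -1.36, and cell proliferation the highest, at 0.94.

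Part of the matrix, macrophage and proliferation genes were higher in the libraries labelled Mrp4 knockout, while the rest did not pass or, in matrix, fell. In extracellular matrix, of 32 genes 18 rose, 1 fell and 13 did not pass. 21 rose and 1 fell when adjusted over the list alone, with a median of 0.62 (camera adjusted p = 2.68e-08, adjusted p = 0.432 with an estimated correlation). Postn, the matrix protein periostin, rose from 34.4 ± 6.75 to 88.2 ± 13.9 FPKM (1.30 ± 0.15, adjusted p = 0.00114), as did the collagen genes Col6a3 (1.04) and Col5a2 (0.81) and the metalloproteinase inhibitor gene Timp1 (1.08). Among macrophage markers, of 22 genes 9 rose, 0 fell and 13 did not pass. 11 rose and 1 fell when adjusted over the list alone, with a median of 0.42 (camera adjusted p = 0.000779, adjusted p = 0.525 with an estimated correlation). The integrin gene Itgax rose from 3.14 ± 1.1 to 9.46 ± 1.16 FPKM, Mpeg1 from 16.8 ± 3.94 to 41.7 ± 6.66 FPKM, Lgals3 from 65 ± 14.2 to 140.0 ± 17.6 FPKM and Ctss from 52 ± 7.33 to 104 ± 24 FPKM. In cell proliferation, of 25 genes 15 rose, 0 fell and 10 did not pass. 16 rose and 1 fell when adjusted over the list alone, with a median of 0.94 (camera adjusted p = 3.97e-06, adjusted p = 0.432 with an estimated correlation). Levels were low: Mki67, a marker of dividing cells, rose from 1.04 ± 0.349 to 2.75 ± 0.714 FPKM, Top2a from 0.912 ± 0.279 to 2.49 ± 0.496 FPKM, Cdc20 from 0.575 ± 0.101 to 1.96 ± 0.787 FPKM and Tpx2 from 0.398 ± 0.103 to 1.22 ± 0.41 FPKM. Among T and NK cell markers, of 16 genes 2 rose, 0 fell and 14 did not pass. 2 rose and 0 fell when adjusted over the list alone, with a median of 0.59 or, without replicate 1 labelled Mrp4 knockout, 0.36 (camera adjusted p = 0.00401, adjusted p = 0.432 with an estimated correlation); Thy1 rose (0.60). Among endothelial markers, of 19 genes 7 rose, 1 fell and 11 did not pass. 9 rose and 1 fell when adjusted over the list alone, with a median of 0.40 (camera adjusted p = 0.00401, adjusted p = 0.612 with an estimated correlation); Cdh5 (0.70) and Tie1 (0.48) rose, beside Tek (0.34, or 0.28 to 0.38 without 1 library, lost in 4) and Plvap (-0.41, or -0.49 to -0.33 without 1 library, lost in 3 and in 1 other setting). Among mesothelial markers, of 15 genes 0 rose, 1 fell and 14 did not pass. 0 rose and 8 fell when adjusted over the list alone, with a median of -0.64 (camera adjusted p = 0.000629, adjusted p = 0.592 with an estimated correlation); Wt1 fell (-1.30 ± 0.24), and Upk1b did not pass (adjusted p = 0.0584).

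Genes tied to what Mrp4 transports moved in small numbers, where 18.3% of all tested genes differed. The shares that differed among cyclic AMP signalling components, CREB target genes and prostaglandin genes were below this. The share among other ABC efflux transporters was above it. The single genes named here are thus no sign that the first 3 lists changed more than other genes. Among cyclic AMP signalling components, of 40 genes 6 rose, 0 fell and 34 did not pass. 8 rose and 2 fell when adjusted over the list alone (camera adjusted p = 0.232). The phosphodiesterase gene Pde7b rose from 1.44 ± 0.513 to 4.05 ± 1.44 FPKM (1.43 ± 0.30, adjusted p = 0.0149) and the adenylyl cyclase gene Adcy7 rose (0.53), beside Pde8a (0.34, or 0.30 to 0.42 without 1 library, lost in 6) and Pde1b (0.63, or 0.52 to 0.82 without 1 library, lost in 6). Among CREB target genes, of 19 genes 0 rose, 2 fell and 17 did not pass. 0 rose and 1 fell when adjusted over the list alone (camera adjusted p = 0.203); Ppargc1a, a coactivator of mitochondrial genes, fell from 1.26 ± 0.32 to 0.655 ± 0.111 FPKM, beside Nr4a1 (-1.23, or -1.65 to -1.06 without 1 library, lost in 5 and in 6 other settings). Among prostaglandin genes, of 25 genes 1 rose, 2 fell and 22 did not pass. 0 rose and 2 fell when adjusted over the list alone (camera adjusted p = 0.61). Over all genes these were Ptges2 (-0.61, or -0.72 to -0.46 without 1 library, lost in 3), Ptges (-1.02, or -1.15 to -0.66 without 1 library, lost in 4 and in 1 other setting) and Ptger2 (0.72, or 0.52 to 0.83 without 1 library, lost in 6). Among other ABC efflux transporters, of 17 genes 5 rose, 0 fell and 12 did not pass. 6 rose and 1 fell when adjusted over the list alone (camera adjusted p = 0.144, fry adjusted p = 0.011). Abcc2, Abcb11 and Abcb4 are transporters of the liver canalicular membrane, and they rose beside liver transcripts in the same libraries. Abcc2 and Abcb11 reached 1.05 ± 0.252 and 1.29 ± 0.492 FPKM, and Abcb4 rose less (0.96, or 0.76 to 1.11 without 1 library, lost in 5 and in 2 other settings). Abcg1 (0.61, or 0.50 to 0.78 without 1 library, lost in 7) also rose.

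Genes best known from liver, some also from kidney or intestine, made up the 12 largest rises. They were Cyp2c37, Cyp4a10, Cyp2a5, Cyp4a14, Ugt2a3, Apoa4, Acsm1, Cyp2c67, Cyp2c29, Cyp2c68, Fabp1 and Mbl2, and all but Cyp2c29 and Fabp1 had 1 to 6 expected counts over the WT libraries together, so their levels are given rather than folds. In the libraries labelled Mrp4 knockout Cyp2c37 was at 2.29 ± 1.06, Cyp4a10 at 2.85 ± 1.08, Cyp2a5 at 2.23 ± 0.975, Cyp4a14 at 3.1 ± 1.22, Ugt2a3 at 1.68 ± 0.686 and Apoa4 at 3.06 ± 1.35 FPKM. Acsm1 was at 1.55 ± 0.664, Cyp2c67 at 1.83 ± 0.522, Cyp2c68 at 1.06 ± 0.168 and Mbl2 at 4.55 ± 1.49 FPKM. Fabp1, the liver fatty acid binding protein gene, rose from 1.86 ± 1.15 to 78 ± 24 FPKM (5.32 ± 0.37, adjusted p = 0.000166), and Cyp2c29 from 0.287 ± 0.269 to 13.6 ± 6.48 FPKM. Among genes at 5 FPKM or more in WT, a group chosen after the data were seen, Alb, which encodes serum albumin, rose from 26 ± 9.75 to 467 ± 107 FPKM (4.10 ± 0.29). Apoa1 rose from 5.85 ± 2.75 to 99.7 ± 26.6 FPKM, Apoa2 from 6.65 ± 2.98 to 159 ± 60.2 FPKM, and Serpina1c, Serpina1e, Serpina3k, Mup20 and Ass1 by 3.98, 2.99, 2.22, 3.79 and 2.20 on the log2 scale. Without replicate 4 labelled Mrp4 knockout the value of Mup20 was 3.11. Mup10 (3.04, or 2.64 to 4.06 without 1 library, lost in 5 and in 1 other setting), Pcbd1 (1.73, or 1.44 to 2.29 without 1 library, lost in 3) and Bmp3 (1.73, or 1.44 to 2.44 without 1 library, lost in 7 and in 1 other setting) rose as well, where the highest value of Mup10 was without WT replicate 1 and that of Bmp3 without WT replicate 2. In a liver list written after these values were seen, of 53 genes 50 rose, 2 fell and 1 did not pass. 50 rose and 2 fell when adjusted over the list alone; the median was 3.79. The 2 that fell, Cyp2e1 and Trf, were at 2528 and 1761 FPKM in WT. In thermogenic adipocyte genes, of 14 genes 2 rose, 1 fell and 11 did not pass. 2 rose and 1 fell when adjusted over the list alone (camera adjusted p = 0.484). Slc27a2 (4.15) and Elovl3 (4.06) rose beside the liver transcripts, and without WT replicate 1 the value of Elovl3 was 4.70. In inflammatory cytokines, of 17 genes 5 rose, 0 fell and 12 did not pass. 5 rose and 0 fell when adjusted over the list alone (camera adjusted p = 0.144); Arg1 (2.58) is also a liver transcript, and among the others were Spp1 (1.64, or 1.37 to 2.15 without 1 library, lost in 2), Ccl5 (0.71, or 0.59 to 0.80 without 1 library, lost in 4) and Ccl8 (0.70, or 0.56 to 0.88 without 1 library, lost in 6).

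**Figure D3:**
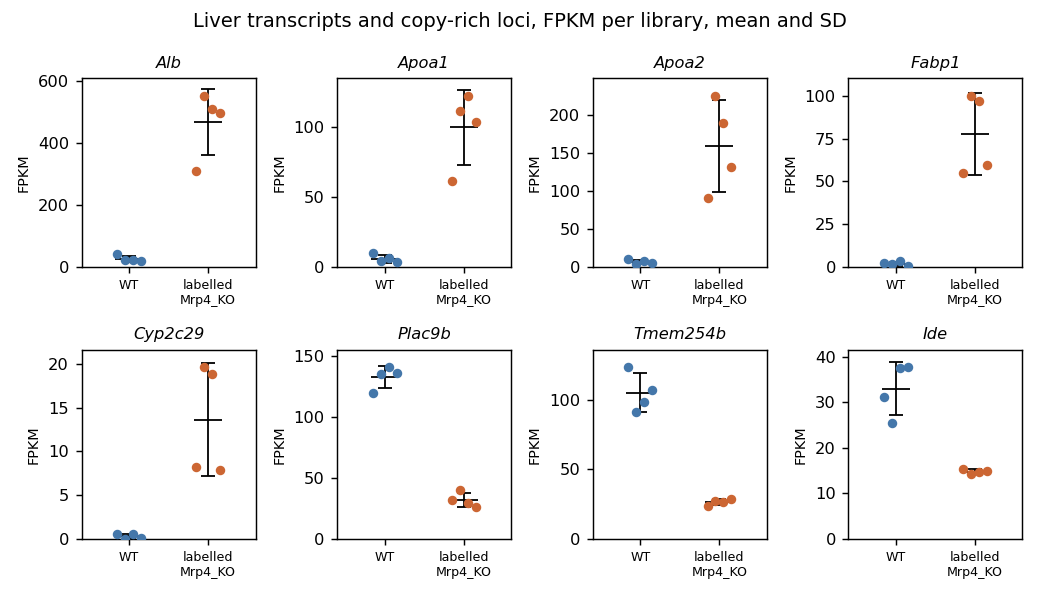
FPKM (vertical axes, linear from 0) of 5 liver transcripts and of Plac9b, Tmem254b and Ide in each library, with WT in blue and libraries labelled Mrp4 knockout in orange. Points are libraries and bars are the mean ± SD of 4. The groups overlap for none of the 8 genes.

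The largest falls outside lipid synthesis included copies that lie beside each other on chromosome 14 in the GRCm38.p6 annotation. Plac9b fell from 133 ± 8.96 to 31.7 ± 5.95 FPKM (-2.13 ± 0.12, adjusted p = 5.17e-05), and Plac9a, Tmem254b and Tmem254a had log2 fold changes of -2.03 ± 0.12, -2.06 ± 0.11 and -2.28 ± 0.35. Copies this alike can share reads, so the division between them is uncertain. Isl1, a LIM homeodomain factor, fell from 1.14 ± 0.527 to 0.278 ± 0.0785 FPKM, and Parm1 from 16.5 ± 10.6 to 4.38 ± 0.618 FPKM, the last with a log2 fold change of -1.46 without WT replicate 1. Among genes beside Abcc4 on chromosome 14, of 22 genes 0 rose, 5 fell and 17 did not pass. 0 rose and 5 fell when adjusted over the list alone (camera adjusted p = 0.144, fry adjusted p = 0.0081). They were Ubac2 (-0.36), Cldn10 (-1.70, or -2.09 to -1.42 without 1 library, lost in 3), Dnajc3 (-0.39, or -0.47 to -0.32 without 1 library, lost in 5 and in 1 other setting), Gpr180 (-0.24, or -0.27 to -0.21 without 1 library, lost in 7 and in 5 other settings) and Dct, chosen after its values were seen, which had 125 counts over the WT libraries and 3 over the others.

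The other lists did not pass camera. Among progenitor and fibroblast markers, of 20 genes 6 rose, 1 fell and 13 did not pass. 7 rose and 2 fell when adjusted over the list alone (camera adjusted p = 0.0703). Lum (0.55), Fap (0.87), Fndc1 (0.71) and Pdgfrb (0.40) rose. Among neutrophil and mast cell markers, of 11 genes 1 rose, 5 fell and 5 did not pass. 1 rose and 7 fell when adjusted over the list alone (camera adjusted p = 0.0639). Kit (0.84) rose, and Elane (-1.23), Mcpt4 (-1.03, or -1.25 to -0.87 without 1 library, lost in 6) and Tpsb2 (-0.92, or -1.15 to -0.71 without 1 library, lost in 6 and in 1 other setting) fell. Among smooth muscle and pericyte markers, of 14 genes 2 rose, 0 fell and 12 did not pass. 2 rose and 0 fell when adjusted over the list alone (camera adjusted p = 0.371). They were Rgs5 (0.82) and Notch3 (0.48, or 0.37 to 0.55 without 1 library, lost in 2). Among B and plasma cell markers, of 14 genes 3 rose, 1 fell and 10 did not pass. 3 rose and 1 fell when adjusted over the list alone (camera adjusted p = 0.203). Igj (-1.43, or -1.75 to -1.18 without 1 library, lost in 5) fell, and Cd79b (0.79, or 0.64 to 0.91 without 1 library, lost in 7) and Fcrla (0.98, or 0.81 to 1.12 without 1 library, lost in 6 and in 1 other setting) rose. Among NRF2 targets, of 20 genes 2 rose, 3 fell and 15 did not pass. 2 rose and 7 fell when adjusted over the list alone (camera adjusted p = 0.326). Hmox1 (0.50) and Ephx1 (0.77) rose, and Tkt (-1.73) and Ces2g (-0.52, or -0.58 to -0.41 without 1 library, lost in 4 and in 1 other setting) fell. Among circadian clock genes, of 21 genes 1 rose, 1 fell and 19 did not pass. 1 rose and 1 fell when adjusted over the list alone (camera adjusted p = 0.674). Hlf (0.70, or 0.55 to 0.80 without 1 library, lost in 3) rose, and the repressor gene Nr1d1 fell from 85.7 ± 15.3 to 44.9 ± 10.6 FPKM. Among glucocorticoid-induced genes, of 17 genes 0 rose, 1 fell and 16 did not pass. 0 rose and 1 fell when adjusted over the list alone (camera adjusted p = 0.194). That gene was Errfi1 (-1.09, or -1.25 to -0.84 without 1 library, lost in 4). Among skeletal muscle transcripts, of 6 genes 0 rose, 2 fell and 4 did not pass. 0 rose and 3 fell when adjusted over the list alone (camera adjusted p = 0.378). One was Actn3 (-1.45, or -1.85 to -1.02 without 1 library, lost in 6 and in 6 other settings), the other Mybpc2, which was below 1 FPKM. Among immediate early and heat shock genes, of 19 genes 0 rose, 0 fell and 19 did not pass. 0 rose and 0 fell when adjusted over the list alone (camera adjusted p = 0.163), and among red blood cell transcripts, of 7 genes 0 rose, 0 fell and 7 did not pass. 0 rose and 0 fell when adjusted over the list alone (camera adjusted p = 0.178). Of the epididymis and testis transcripts 2 were tested, too few for the list test.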

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

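In 18 of 286 group values, 1 library lay far from the other 3 of its group, where chance sets apart about 1 in 20 (14.3 values). WT replicate 2 lay apart for Lep (508 FPKM against 138 to 183), Pde7b (2.21 FPKM against 1.14 to 1.22) and Wt1 (9.28 FPKM against 15.3 to 15.9), each time on the side of the libraries labelled Mrp4 knockout. WT replicate 1 lay apart for Ptges (58.2 FPKM against 24.9 to 30.2), Akt2 (174 FPKM against 155 to 157) and Ctss (41.2 FPKM against 54 to 56.6), and near the floor for Cyp2a5 (0.08 FPKM against 0 to 0), Acsm1 (0.1 FPKM against 0 to 0) and Ugt2a3 (0 FPKM against 0.03 to 0.03). WT replicate 3 lay apart for Cyp2c37 (0.04 FPKM against 0 to 0). Replicate 5 labelled Mrp4 knockout lay apart for Pcbd1 (54.9 FPKM against 29.1 to 30.9), Abhd5 (53.2 FPKM against 38.9 to 41.2) and Ces1f (57.2 FPKM against 43.1 to 44). Replicate 1 labelled Mrp4 knockout lay apart for Timp1 (8.42 FPKM against 6.65 to 6.95), Pdgfrb (28.4 FPKM against 23.5 to 23.7) and Tek (24.4 FPKM against 20.6 to 20.8), replicate 2 labelled so for Srebf1 (75.3 FPKM against 68.6 to 69.1), and replicate 4 labelled so for Gpam (75.7 FPKM against 50.9 to 55). The causes were not tested.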

How the results depend on the processing

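The liver score as covariate, the liver transcripts left out and the length trend removed were chosen after seeing the data. The total of 2606 genes past the threshold was 2126 to 3351 over the other scalings, filters, tools and FPKM fits, but the 1148 lower genes became 680 with library size alone, 652 and 648 with limma on log2(FPKM + 1) and log2(FPKM + 0.1), and 495 with every gene above 0, where 74.1%, 71.1%, 71% and 76.7% of calls were higher. An adjusted p under 0.01 left 551 genes (398 higher, 153 lower), and a log2 fold change of at least 1 left 663 (538 and 125), as stricter thresholds do. Leaving out 1 library gave 1172 (without WT replicate 4) to 3683 genes (without WT replicate 2), with 720 to 1977 higher and 452 to 1706 lower; fewer samples account for part of the fall. The replicate number as a block left 141 genes (110 higher, 31 lower) and 18 lists. Only numbers 1, 2 and 4 occur in both groups, so WT replicate 3 and replicate 5 labelled Mrp4 knockout add nothing to that comparison. The block also takes up degrees of freedom, so losses under it can reflect less power and do not show an effect of pairing. Deviations of libraries with the same number correlated at 0.09, -0.03 and -0.15, and those of libraries with different numbers at -0.13 to 0.289. These values show no pairing by number, but so few pairs cannot exclude one. The liver score, nearly collinear with the groups, left 1 gene in edgeR (0 higher, 1 lower, 1660 at an unadjusted p under 0.05) and 18 lists. It reversed Abcb11 (-1.57), Abcb4 (-0.72), Slc27a2 (-0.18), Elovl3 (-3.22), Serpina1c (-0.62), Serpina1e (-0.72), Serpina3k (-1.62), Mup20 (-2.26) and Mup10 (-3.60), and these genes did not pass. The median log2 fold change of the list thermogenic adipocyte genes also reversed (-1.41, camera adjusted p = 0.031). Without the liver transcripts 2554 genes passed. Against 11 lists of 33, 0 passed camera with an estimated correlation (2 at an unadjusted p under 0.05) and 15 passed fry. Under fry 3 lists lost the call: cholesterol synthesis, endothelial markers and mesothelial markers (fry adjusted p = 0.194, 0.096 and 0.125). Another 7 gained it, among them genes beside Abcc4, other ABC efflux transporters and lipolysis (fry adjusted p = 0.0081, 0.011 and 0.039). With the length trend removed 11 lists passed camera, and 11 to 17 passed it without 1 library. Abcc4 changed sign without passing: 0.0182 with library size alone, 0.0284 and 0.0353 with limma on log2(FPKM + 1) and log2(FPKM + 0.1), 0.0284 with every gene above 0 and 0.0148 with the block. Without 1 library it kept its sign, at -0.0875 to -0.0129. Of 139 other named genes 138 passed, of which 41 lost the call without at least 1 library and 116 under the block. With the liver score all 138 lost it, 129 on the same side and 9 with the sign reversed. Calls were also lost in 4 with library size alone, 4 with upper quartile factors, 5 with no filter beyond 1 count in all samples together, 1 with limma-voom, 6 and 6 with limma on log2(FPKM + 1) and log2(FPKM + 0.1), and 13 with every gene above 0, and 0 genes reversed under the alternatives fixed in advance. Apart from the effects of fewer samples and stricter thresholds, the cause was not tested.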

Other observations

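The tests of Abcc4, of liver transcripts and of the Plac9 and Tmem254 genes below, their bounds, the MHC class II list and Kdelc2 were chosen after the results they bear on had been seen; the count over splits was planned for genes and lists and added for Gene Ontology terms, but its bound was written down after the result. In the MHC class II list, of 10 genes 8 rose, 0 fell and 2 did not pass. 9 rose and 0 fell when adjusted over the list alone, with a median of 0.87 (camera adjusted p = 9.37e-09, adjusted p = 0.0603 with an estimated correlation). These camera values were adjusted only over this list and the liver list, both written after the data were seen. They cannot be set beside those of the lists fixed in advance. H2-Aa rose from 245 ± 35.6 to 484 ± 43.4 FPKM and H2-Eb1 from 99.8 ± 11.9 to 205 ± 24.4 FPKM, and the invariant chain gene Cd74 (0.79) and Ciita, the activator of this class (1.06, edgeR adjusted p = 0.00305), also rose. Of 1792 Gene Ontology terms tested with camera at the preset correlation, 71 passed higher and 80 lower, and 0 passed with an estimated correlation. Among those at the preset correlation, antigen processing and presentation of exogenous peptide antigen had 8 of 13 genes higher, and the spliceosomal complex 24 of 116 lower and 1 higher, with a median of -0.16. Kdelc2 on chromosome 9 rose from 10.5 ± 0.706 to 23.7 ± 2.31 FPKM.

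The labelled groups gave 2606 genes. Of the 35 splits of the libraries into 4 and 4, 1 reached this count, itself, and the highest other gave 0 genes in edgeR. This argues against a random division of these libraries as the source of the gene count. The share, 1 of 35, is the smallest possible, and every other split mixes the labelled groups. The count does not tell genotype from another difference between the groups. Chance stays open for lists: the labelled groups gave 11 lists, 17 of the 35 splits gave at least as many, and the highest other gave 19. It also stays open for Gene Ontology terms: 4 of the 35 splits gave at least as many as the labelled groups (151), and the highest other gave 163.

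Abcc4 was alike in both groups. Over the other genes, 0 libraries correlated better with the other group than with their own. This argues against a swap of single libraries only if genotype, rather than handling, sets the groups apart, which was not tested. An exchange of the labels of the whole groups would leave Abcc4 different between them only if the altered allele lowers its count. In that case alone the upper end of the 95% interval of its fold, 1.11, argues against an exchange. In the same case the lower end, 0.843, argues against the labels as given, so the interval favours neither. Otherwise an exchange stays open. A label wrong for a whole group is not decided by these values and stays open. Reads of other genes counted as Abcc4 stay open: its expected count was fractional in 0 of 8 libraries, but reads assigned to it alone would be whole as well. An altered allele that still makes the counted part of the transcript cannot be told apart from a normal gene, because a fold of 0.966 per gene shows no exons. Flanking DNA of another strain stays open: 22.7% of the neighbours passed against 18.3% of other genes (Fisher's exact p = 0.581), all of them lower (Fisher's exact p = 0.0279 for lower genes alone).

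Most listed liver transcripts were higher in the libraries labelled Mrp4 knockout, with Alb at 618 to 1103 counts per 1e6 against 34.8 to 79.6 in WT. The whole liver list was not higher, at 0.849% to 1.19% of the counts against 0.9% to 1.37% in WT. Without the 4 genes at 20 FPKM or more in WT it was at 0.13% to 0.261% against 0.0097% to 0.0273%. These 4 include Alb (26 FPKM in WT), which rose, and Cyp2e1 and Trf, which fell and were far higher in WT. The total of the whole list therefore does not follow most of its members. RNA of several abdominal organs together stays open: 2.78% of the listed pancreas, kidney and intestine transcripts passed higher (1 of 36, of which 3 were tested), and the untested ones decide nothing. Dilution by liver RNA as the reason for the lower lipid synthesis genes is argued against, since the adipocyte identity list had a median of -0.060 and fatty acid synthesis one of -1.36; without 1 library these were -0.16 to -0.04 and -1.53 to -1.08. Liver tissue or liver RNA in these libraries is a candidate explanation that stays open: 94.3% of the tested liver transcripts rose. The list was written after many of them had been seen to rise, so this share decides nothing. In the WT libraries 4 of them were at 20 FPKM or more, and their source there was not tested. Liver genes switched on in the fat by the genotype were not tested and stay open, as does tissue collection, which the labels do not describe by group.

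Plac9a, Tmem254a, Tmem254c, Plac9b and Tmem254b lie in a row and all fell. Their summed counts had a log2 fold change of -2.07 (exact permutation p = 0.0286, the smallest possible). The run was picked as genes called lower, so a lower sum was fixed in advance and the p-value adds nothing. A shift of reads among these 5 genes alone would raise some as others fell, which the fall of all 5 argues against. Reads going to copies outside these 5 were not tested, so that stays open. A run as long arose in 48 of 1000 shuffles of the calls over gene positions, at the border of the threshold; under 0.05 was the bound first written, and chance neighbours were left open only after this value was seen, since its 95% interval of 3.64% to 6.31% spans 5% and copies that share reads are not independent. A difference in copy number between the mice may explain the run and stays open, with a median of -0.11 in the 5 tested genes on the side that differed more, since no DNA was read. On chromosome 19, Ide fell from 33 ± 5.85 to 14.8 ± 0.499 FPKM (-1.23 ± 0.12), as did Fgfbp3 (-1.45) and Btaf1 (-0.58), with Cpeb3 (-0.24) and March5 (-0.26) between them not past the threshold and 4931408D14Rik (-1.65) between them lower. Of the next 5 tested genes on the other side of Ide, Kif11 (0.94), Hhex (0.65), Exoc6 (0.34) and Cep55 (1.46) rose and Myof (0.03) did not pass. A segment with Ide and Fgfbp3 is known to vary in copy number among C57BL/6J mice, which was not tested here.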
